A study of Mus musculus with 12 samples.

How the data were processed

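Bone marrow cells from wild-type (WT) mice and from mice with a conditional knockout (cKO) of Ythdf2 were grown for 7 days with 20 ng/ml M-CSF, a growth factor that turns them into macrophages. They were then stimulated for 24 hours with 100 ng/ml LPS and 20 ng/ml interferon gamma to give M1-type macrophages, per the labels' protocols. The series holds 12 libraries in 6 groups of 2. For m6A sequencing, polyadenylated RNA was cut into fragments of about 100 nucleotides, and fragments carrying N6-methyladenosine (m6A) were pulled down with an antibody. Immunoprecipitated and input libraries were made for WT and for cKO. For RNA immunoprecipitation, RNA bound to the YTHDF2 protein was pulled down with 5 µg of antibody from WT macrophages, with its own input. The labels number 2 replicates in each group and do not say whether these came from separate mice or cultures, so the p-values may measure technical spread alone.

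Altogether 3 deposited files were used, and 0 of them held values per library. The first is a comparison of the m6A input libraries of both genotypes. Its columns, per the file headers, carry the names that DESeq2 gives its results. Its mean normalized count is a signal the authors made by averaging counts over libraries after division by size factors, per the file headers and the values. Its log2 fold change and standard error were given by the authors, per the file headers. The Wald statistic, a score the authors deposited, equalled the log2 fold change over its standard error to rounding. The p-value and adjusted p-value columns were deposited by the authors, and the adjusted values equalled a Benjamini-Hochberg adjustment over the 10778 genes that have one. Those genes had a mean normalized count of at least 48.0, and the other 16235 of the 27013 genes had no adjusted p. The direction of the fold change is not given in the sources used here. The second file lists WT m6A peaks by Ensembl gene, start, end, strand and symbol, with no chromosome, level or p; its name and the labels name exomePeak2. The third lists YTHDF2 peaks with a ratio that the authors deposited as the fold enrichment at the summit, a −log10 p and −log10 q that the authors deposited in the usual narrow-peak order, and the transcript features each peak overlaps. Its score column, as deposited, is the integer part of 10 times the −log10 q. The peak caller is not given in the sources used here. Both peak lists are single lists for the WT group, so replicates had been pooled or combined before deposit. HISAT2, HOMER, ChIPseeker and the mm10 build are named in the submitters' processing notes with no role or version. The cKO m6A peaks were not analysed here.

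The depth of each library is not in the files used. The lowest mean counts in the authors' deposited table repeated 4 values, as single reads in 4 libraries would give. With 4 libraries, these values give size factors of 1.28 and 0.884 on the negative side and 0.972 and 0.924 on the positive side, so the highest was 1.45 times the lowest. All 10 sums of 2 such steps were found in the table. The standard error of the log2 fold change had a median of 0.167 among tested genes, with 5th and 95th percentiles of 0.115 and 0.427.

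Gene symbols of the peak lists were joined to the expression table directly or through synonyms in a RefSeq gene table of the GRCm38.p6 assembly (the same coordinates as mm10). Of 5447 genes with an m6A peak, 5160 were in the expression table, and of 7598 genes with a YTHDF2 peak 7339 were, 614 of them through a synonym. Gene coordinates come from the RefSeq table and peak coordinates from the deposited lists, all written 1-based. The YTHDF2 list held 45541 rows, of which 3234 were repeats and were dropped, leaving 17843 distinct peaks. A summit was placed in the 3′ UTR, coding sequence, 5′ UTR or intron of the transcript the list names, in that order where it names several. An m6A peak was placed on a chromosome when it lay within 1000 bp of the RefSeq gene of the same symbol, as 9289 of 10290 did. A fold enrichment was used only to rank and filter peaks within the YTHDF2 list.

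Gene lists (21 pathway or control lists and 8 lists of cell type markers), the tests and the rule for named genes were fixed before the data were examined. The design foresaw counts per library. With the authors' comparison only, their fold changes and p-values are described, and every call of a gene is theirs (adjusted p under 0.05). The 24 lists with at least 3 tested members were tested against all other tested genes with the cameraPR test of limma 3.58.1 in R 4.3.3 on the Wald statistic, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Genes with m6A peaks, YTHDF2 peaks or both were tested the same way, as 3 sets. A correlation between genes could not be estimated, since this needs values per library. The size of a shift was measured against 10000 random gene sets matched in 20 bins of mean normalized count. Random sets were drawn from all genes of a bin, members of the set included. For large sets, a shift therefore understates the distance from genes outside the set, and more so the larger the set. These permutation results cannot give a p below 0.0002. Overlaps of gene sets were tested with Fisher's exact test, two-sided, among tested genes. Shares of peaks carry 95% Wilson intervals, which cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

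The set test was tested on simulated data for the 10778 genes, with lists shifted by known amounts and noise from the deposited standard errors. Lists shifted by 0.1 on the log2 scale were called in 65% of 20 cases, by 0.2 in 100%, by −0.2 in 95% and by 0.4 in 100%. Lists with no shift were called in 1.03% of 291 cases. Sets picked by expression, simulated on the same genes, fell outside the matched random sets in 0% of 20 cases with no shift and in 100% with a shift of 0.05. Noise was drawn separately for each gene, so both simulations leave out correlation between genes. They cannot show how often sets of correlated genes are called without a shift. For the matched sets, 0.05 was the amount added to the set's own genes, and smaller amounts were not simulated. The random sets held such genes too, so the shift measured against them would be smaller than 0.05. That measured shift was not recorded, so 0.05 cannot be set against the shifts reported below.

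The named genes are Ythdf2, the 10 largest changes on each side with adjusted p under 0.05 and a mean count above the tested median of 739, up to 6 members per list, the 10 genes with the highest YTHDF2 fold enrichment, the 3 genes with most peaks per list, up to 10 positive and 5 negative changed genes with both kinds of peak, and up to 8 members with both peaks in each of the MHC lists and of 1 list that is not reported here. The part of the rule that asks whether both cKO libraries lie beyond both WT libraries could not be applied. Alternatives were no filter on low counts, a mean count of at least 50, other thresholds, stricter peak sets, other overlap rules, another background, and matched random sets. Added after seeing the data were the upper 50% of genes by expression, centring on the most abundant 25% of genes, correlations of 0.05 and 0, ranks, exonic peaks for gene sets, genomic span, lists without interferon genes, and counts of lists among peaks against matched genes. Left out for want of values per library were other normalizations and pseudocounts, each left-out library, a replicate block, an estimated correlation and the fry test. Stricter m6A peaks could not be taken because that list has no level. The motif of m6A sites and transcript lengths need a genome sequence and transcript models that were not used here.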

Results

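The study asked how loss of YTHDF2, a protein that reads m6A marks on mRNA and promotes the decay of marked transcripts, affects inflammatory macrophages, and which transcripts carry the mark or are bound. It measured M1-type macrophages grown from mouse bone marrow in 12 libraries. Input RNA was compared between WT and Ythdf2 cKO cells (2 libraries each), m6A peaks were mapped in WT cells, and YTHDF2-bound RNA was mapped in WT cells. All fold changes and their standard errors below come from the authors' deposited table, and the depth of each library is unknown. That table does not state which genotype is the numerator. A positive value is therefore called the side of Ythdf2, since Ythdf2 itself was positive, and a negative value the opposite side. If positive means more RNA in WT, Ythdf2 RNA was lower in cKO cells and so was every gene called positive here; if it means more RNA in cKO, the reverse holds.

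Ythdf2, the targeted gene (chromosome 4, 132184916 to 132212256, mm10), had a log2 fold change of 1.10 ± 0.16 (SE) in the authors' deposited table, with an adjusted p of 2.1e-09 from their Wald test and a mean normalized count of 1762. Its transcript carried 2 m6A peaks, at 132204871 to 132205120 and 132205171 to 132205520, and no YTHDF2 peak. Other members of the m6A machinery did not pass the test. Ythdf1, a reader of the same family, was at −0.00 ± 0.13 and Ythdf3 at 0.08 ± 0.13 in the authors' deposited table (both chosen after their values were seen). Igf2bp2 was at 0.32 ± 0.15 and the demethylase Alkbh5 at 0.22 ± 0.13. Of the 19 tested writers, erasers and readers, Ythdf2 was the 1 that passed, also adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.093).

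In the comparison of the genotypes, 250 of 10778 tested genes passed an adjusted p of 0.05 in the authors' deposited table, 190 on the side of Ythdf2 and 60 on the opposite side. At an unadjusted p under 0.05 there were 677 and 400. Most changes were small: 25 positive and 8 negative genes reached 2-fold, and the median log2 fold change of changed genes was 0.64 on one side and −0.59 on the other. Asking for at least 1.5-fold left 115 and 30 genes. With fold changes centred on the most abundant 25% of genes (median 0.04), 146 and 75 genes passed, so the positive share was 66.1% in place of 76%. Of the called genes named below, Cflar, Traf1, Klf4, Cd68, Col1a1 and Mill2 lost the call both with no filter on low counts (adjusted p 0.055 to 0.12) and with this centring (adjusted p 0.057 to 0.091). Vsir, Gpnmb, Rpl3, Rpsa and 3110082I17Rik lost it with no filter alone (adjusted p 0.052 to 0.10).

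**Figure D1:**
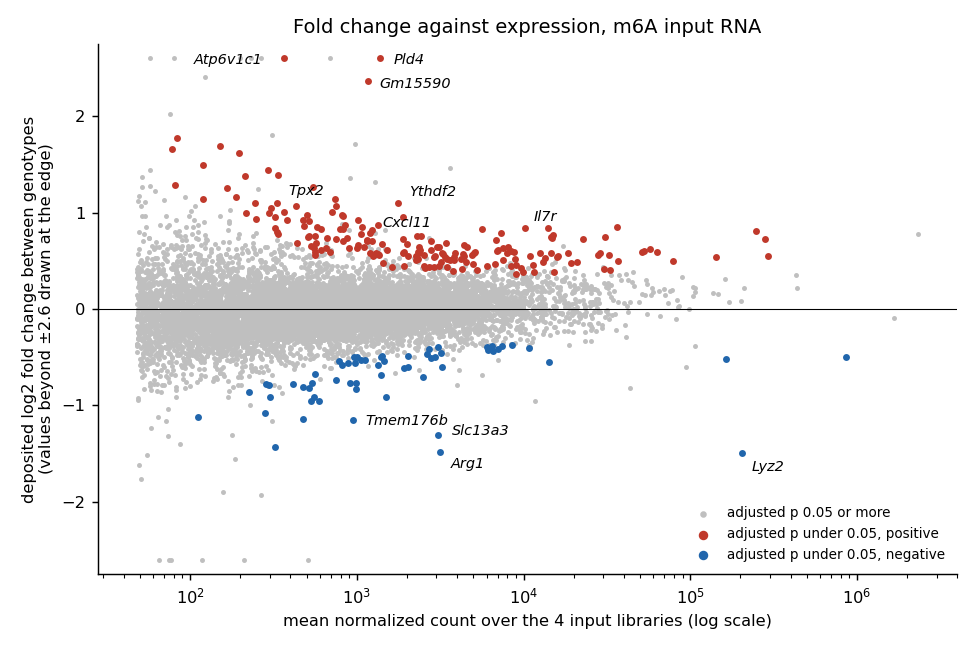
Each point is 1 of 10778 tested genes; the x axis is the mean normalized count on a log scale and the y axis the deposited log2 fold change between genotypes, with no direction stated by the authors. The 190 red genes are positive and the 60 blue genes negative at adjusted p under 0.05; Ythdf2 lies at 1.10 and Lyz2 at −1.49.

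The largest positive change by the rule was that of Pld4, a phospholipase-family exonuclease of endolysosomes, at 6.03 ± 0.53 in the authors' deposited table (adjusted p 1.5e-26). Gm15590 followed at 2.37 ± 0.60 (adjusted p 0.0065). Tpx2, a spindle assembly factor, was at 1.07 ± 0.21, and Clic5 at 0.98 ± 0.20. Ly75, an endocytic receptor of antigen-presenting cells, was at 0.97 ± 0.20, and Tent5c, a poly(A) polymerase, at 0.96 ± 0.19. Rassf8, Adra1a and Plpp3 lay at 0.93, 0.87 and 0.87, each with an adjusted p of 0.00044 or less. Atp6v1c1, a subunit of the proton pump of lysosomes, was at 4.39 ± 0.27 (adjusted p 4.4e-54); it fell outside the rule because its mean count was 368, and was chosen after its values were seen.

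On the opposite side, the largest change was that of Lyz2, the lysozyme gene of macrophages (chromosome 10, 117277541 to 117282272), at −1.49 ± 0.33 (adjusted p 0.0013) in the authors' deposited table, at a mean count of 204979. Arg1, the arginase that competes with nitric oxide synthase for arginine, was at −1.48 ± 0.37 (adjusted p 0.0063). Slc13a3, a carrier of dicarboxylates, was at −1.31 ± 0.13 (adjusted p 7.4e-21), and Tmem176b at −1.15 ± 0.15 (adjusted p 2.6e-11). Sema4c was at −0.91 ± 0.16 and the collagenase Mmp8 at −0.83 ± 0.19. The integrin Itga9, the iron carrier Trf, Man2a2 and Gm5150 lay between −0.77 and −0.71, all with an adjusted p of 0.0018 or less.

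Genes of the type I interferon list were on the side of Ythdf2. Of 27 tested genes of the type I interferon response, 9 passed on that side and none on the other (10 adjusted over the list alone), and all 27 values were above 0. In the authors' deposited table the antiviral genes Cmpk2, Oasl1, Ifit3, Ifit1, Rsad2 and Isg15 lay at 0.60, 0.58, 0.56, 0.56, 0.53 and 0.49, each with an SE of 0.10 to 0.13. The list's median was 0.26, and limma's cameraPR gave an adjusted p of 2.5e-18. With a preset correlation of 0.05 this became 4.0e-10, and expression-matched random sets gave an adjusted p of 0.0027. Other interferon-induced genes that passed on the same side were the chemokines Cxcl11 at 0.82 ± 0.14, Cxcl9 at 0.62 ± 0.15 and Cxcl10 at 0.55 ± 0.13, which draw T cells, the guanylate-binding proteins Gbp4, Gbp5, Gbp3 and Gbp2 at 0.64, 0.64, 0.58 and 0.58 and Gbp7 at 0.40, and Cd274, which encodes PD-L1, at 0.42 ± 0.10. Some Gbp, Ifit and H2-Q genes have near-identical copies, and the counting of shared reads is not given in the sources used here.

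Genes of antigen presentation leaned the same way. Of 23 tested MHC class I genes, H2-Q6 at 0.77 ± 0.15 and H2-Q7 at 0.59 ± 0.16 passed in the authors' deposited table, both near-identical paralogs, and 6 passed adjusted over the list alone. The classical genes H2-K1 and H2-D1 were at 0.32 ± 0.12 and 0.21 ± 0.12, neither past the threshold. The list had an adjusted p of 1.1e-04, but 0.073 against expression-matched random sets. Of 11 MHC class II genes none passed over all genes and 1 did adjusted over the list alone. H2-Aa was at 0.55 ± 0.18 (adjusted p 0.098) and the invariant chain Cd74 at 0.26 ± 0.17. That list had an adjusted p of 0.030, which became 0.084 with a preset correlation of 0.05 and 0.26 in the upper 50% of genes by expression. Ciita, the regulator of MHC class II genes, had a mean count of 17 and no adjusted p.

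Chemokines and their receptors were positive as a list (adjusted p 1.3e-06; 4 of 22 passed, 5 adjusted over the list alone), with Ccrl2, a chemokine-binding receptor, at 0.64 ± 0.12 beside Cxcl9, Cxcl10 and Cxcl11 in the authors' deposited table. The proinflammatory M1 list was positive too (adjusted p 2.6e-04), with the same Cxcl9, Cxcl10 and Cxcl11 on one side and the acute-phase gene Saa3 at −0.49 ± 0.12 on the other; of 29 genes, 3 passed on the first side and 1 on the second, or 5 and 1 adjusted over the list alone. Without interferon response genes it was no longer called (adjusted p = 0.082). Among 26 apoptosis genes, Cflar, an inhibitor of caspase-8, passed at 0.38 ± 0.11, and 4 positive and 1 negative member passed adjusted over the list alone (list adjusted p 3.1e-04). Among 24 genes of the NF-kB pathway, Traf1 passed at 0.47 ± 0.14, and was also the 1 that passed adjusted over the list alone. That list's adjusted p of 0.036 became 0.14 with a preset correlation of 0.05, 0.11 against matched random sets, 0.18 in the upper 50% of genes and 0.059 with centring.

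Lists of housekeeping and metabolic genes were on the opposite side. All 32 ribosomal protein genes had values below 0, with a median of −0.29 and a cameraPR adjusted p of 3.2e-18 (1.4e-09 with a preset correlation of 0.05). Rpl3 at −0.60 ± 0.17 and Rpsa at −0.44 ± 0.13 passed over all genes in the authors' deposited table, and 18 passed adjusted over the list alone; these genes have many processed copies in the genome. Of 19 glycolysis genes, 17 lay below 0 and none passed over all genes, while 1 did adjusted over the list alone. The kinase Pdk1 was at −0.59 ± 0.19 and lactate dehydrogenase Ldha at −0.21 ± 0.10 (list median −0.14, adjusted p 6.3e-04). Of 26 genes of oxidative phosphorylation none passed, also adjusted over the list alone, and 19 lay below 0. Cytochrome c, Cycs, was at −0.33 ± 0.12 (list median −0.09, adjusted p 0.018, or 0.096 with a preset correlation of 0.05). Uqcrc1 and Atp5a1, at −5.10 ± 2.25 and 4.46 ± 2.15, were too imprecise to place.

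**Figure D2:**
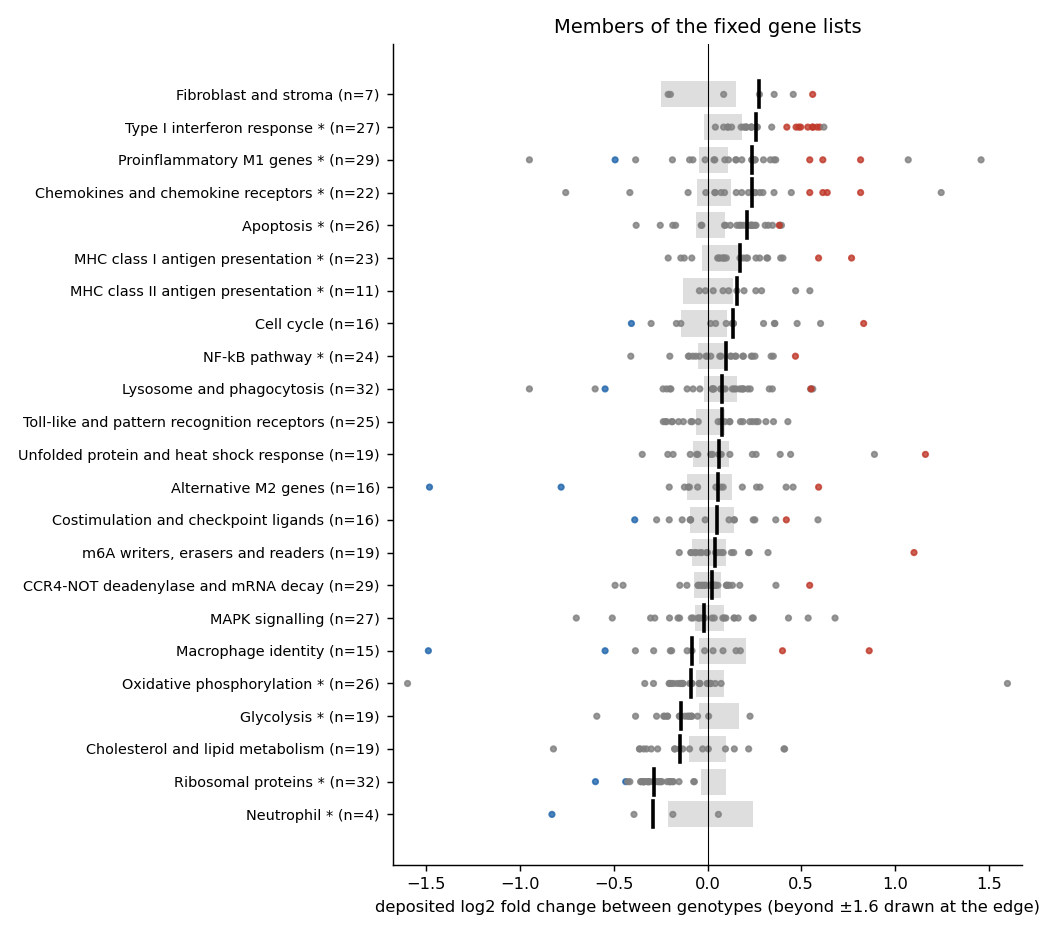
Each point is a tested member of 1 of 23 fixed gene lists at its deposited log2 fold change (x axis), red or blue where its adjusted p was under 0.05; the black bar is the list's median, the grey band holds 95% of 10000 expression-matched random medians, and a star marks a cameraPR adjusted p under 0.05. The type I interferon list has a median of 0.26 and ribosomal proteins one of −0.29.

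Other lists were not called as a whole by cameraPR. Among 16 genes of alternative (M2) activation, Arg1 and the mannose receptor Mrc1 (−0.78 ± 0.21) were negative and Klf4 positive (0.59 ± 0.17) in the authors' deposited table, with 2 positive and 2 negative adjusted over the list alone (list adjusted p 0.78). Among costimulation and checkpoint ligands, Cd274 passed on one side and Vsir, which encodes the checkpoint ligand VISTA, on the other at −0.39 ± 0.11 (3 and 1 adjusted over the list alone; list adjusted p 0.17). Zfp36l2, which recruits the deadenylase complex, was at 0.55 ± 0.14 and was the 1 called member of 29 genes of mRNA decay, also adjusted over the list alone (list adjusted p 0.53). Hspa1b, a heat shock protein, passed at 1.16 ± 0.27 and was 1 of 2 adjusted over the list alone among 19 stress genes (list adjusted p 0.095). Among 32 lysosome and phagocytosis genes, Gpnmb was at 0.55 ± 0.15 and Itgam, the integrin CD11b, at −0.55 ± 0.11 (4 and 1 adjusted over the list alone; list adjusted p 0.13). In the cell cycle list Mki67 was at 0.83 ± 0.19 and the cell cycle inhibitor Cdkn1a at −0.41 ± 0.11 (2 and 1 of 16 adjusted over the list alone; list adjusted p 0.17). None of 27 MAPK genes or 25 pattern recognition receptors passed, over all genes or over the list alone (list adjusted p 0.69 and 0.13); Dusp4 was at 0.68 ± 0.22 and Tlr9 at 0.43 ± 0.15. Of 19 genes of cholesterol and lipid metabolism none passed over all genes, while 2, on the positive side, did adjusted over the list alone: Abcg1 at 0.41 ± 0.14 and Mylip at 0.41 ± 0.14. That list's median was −0.15, the opposite sign (adjusted p 0.44).

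Markers of other cell types were few. Of 15 macrophage markers, Lyz1 at 0.86 ± 0.18 and Cd68 at 0.40 ± 0.11 were positive and Lyz2 and Itgam negative in the authors' deposited table (2 and 3 adjusted over the list alone; list adjusted p 0.18). Of 12 neutrophil markers, 4 were tested, with Mmp8 past the threshold and S100a8 at −0.39 ± 0.26, S100a9 at −0.18 ± 0.27 and Csf3r at 0.06 ± 0.13 (1 adjusted over the list alone; list adjusted p 0.030). That call was lost with no filter (adjusted p 0.060), with a preset correlation of 0.05 (adjusted p 0.051) and by ranks (adjusted p 0.15). Of 7 tested fibroblast and stroma markers, Col1a1 was at 0.56 ± 0.17, the 1 that passed, and Col1a2 at 0.46 ± 0.17 (2 adjusted over the list alone; list adjusted p 0.066). T and NK cell markers left 1 tested gene, Cd4 at 0.79 ± 0.25, which did not pass over all genes and did adjusted over the list alone. B cell markers left 2, Blnk at 0.25 ± 0.13 and Cd79b at −0.94 ± 0.48. Erythroid markers left 1, Car2 at 0.14 ± 0.48. Neither of the last lists had a call adjusted over the list alone. No dendritic cell or mast cell marker was tested. The 7 features, chosen after their values were seen, that resemble ribosomal RNA or hold its sequence lay between 0.72 and 0.85 in the authors' deposited table and made up 9.41% of the summed mean normalized counts, on the same side as the type I interferon list. CT010467.1 alone made up 7.53% and did not pass (0.77 ± 0.37, adjusted p 0.44); the other 6 passed and made up 1.88%.

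In WT macrophages, 10290 m6A peaks lay in 5447 genes, with 1 peak in 2870 genes and more in 2577. Their genomic span had a median of 325 bp and a highest value of 9999 bp, since a peak can cross introns. Ahnak, a giant scaffold protein (chromosome 19, 8989284 to 9076935), carried the most, 20 peaks, followed by Bod1l and Macf1 with 15 each. In the authors' deposited table these 3 genes were at 0.27 ± 0.14, 0.07 ± 0.12 and 0.05 ± 0.11, none past the threshold. Of tested genes, 4888 carried an m6A peak.

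The list deposited as YTHDF2 peaks held 17843 peaks in 7598 genes. Whether it holds peaks of the m6A libraries stays open, as described in the closing section. Of 17621 summits that fell in an annotated feature, 39.2% lay in a 3′ UTR, 35.7% in coding sequence, 2.02% in a 5′ UTR and 23.1% in an intron. The deposited list names 1 transcript for 99.7% of its genes, so an exon of another transcript can count as intron. Introns held more of the stronger peaks: 33.7% of summits in the strongest 25% by the authors' fold enrichment, against 33.2% in 3′ UTRs. The fold enrichment had a median of 3.01 and ranged from 1.39 to 15.5. Among tested genes the highest values were those of Zfp970 at 15.5, Fam91a1 at 14.9, Psmg2 at 13.3 and Eif2s3x at 12.99, with Calcoco1, Vwf, Sccpdh, Unc5a, Adk and Dusp8 between 12.3 and 11.4. Of these, Vwf, von Willebrand factor, was at 0.64 ± 0.18 and Adk, adenosine kinase, at −0.77 ± 0.17 in the authors' deposited table, both past the threshold. Most peaks lay in Gm20388 with 111, Herc2 with 41 and Ubr4 with 34. The latter pair, both ubiquitin ligases, were at −0.15 ± 0.12 and 0.12 ± 0.11.

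Genes with m6A and genes bound by YTHDF2 overlapped. Of 4888 tested m6A genes, 3861 (79.0%) had a YTHDF2 peak, against 52.6% of the other genes (odds ratio 3.39, two-sided Fisher's exact p = 1.7e-184). Both kinds of peak were found more often in highly expressed genes: 8.0% of genes in the lowest 10% by expression had an m6A peak and 17.7% a YTHDF2 peak, against 68.4% and 89.3% in the highest. Expression-matched random genes gave an expected overlap of 3696 (95% of sets between 3658 and 3734), so the observed count was 1.04 times that. The random genes were drawn from all tested genes, m6A genes among them. The ratio therefore understates any excess over matched genes without m6A. By position, 49.0% of 9289 placed m6A peaks overlapped a YTHDF2 peak by at least 1 bp (95% Wilson interval 48.0 to 50.0), and 23.1% of YTHDF2 peaks overlapped an m6A peak. The share expected by chance in the same transcripts was not estimated.

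**Figure D3:**
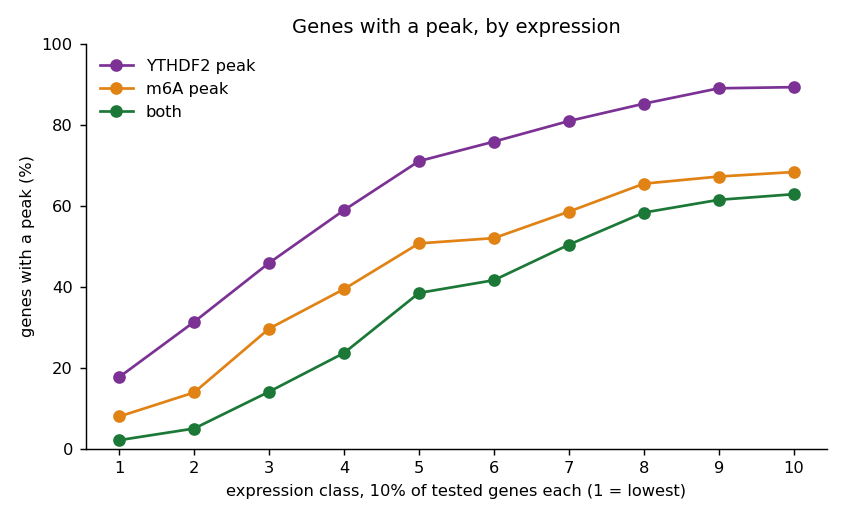
The x axis is the rank class of mean normalized count, each with 10% of the tested genes, and the y axis the percent of its genes with a YTHDF2 peak, an m6A peak or both (lines). The share with an m6A peak goes from 8.0% in the lowest class to 68.4% in the highest.

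Single genes show how the marks lie. In Cd274 (chromosome 19), m6A peaks at 29382531 to 29385798 and 29386724 to 29387148 overlapped YTHDF2 peaks at 29385265 to 29386248 and 29386485 to 29387946, both with summits in the 3′ UTR and fold enrichments of 2.03 and 1.70. In Gbp5 (chromosome 3), an m6A peak at 142518978 to 142521457 overlapped a YTHDF2 peak at 142521321 to 142521583 in the 3′ UTR, with a fold enrichment of 1.89. Irf1 (chromosome 11) had an m6A peak at 53773588 to 53773762 inside a YTHDF2 peak at 53773492 to 53774381 whose summit lay in coding sequence. Cxcl10 (chromosome 5) had an m6A peak at 92348563 to 92348612 apart from its YTHDF2 peak in the 3′ UTR at 92347002 to 92347478. These genes were chosen after their values were seen.

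Among the fixed lists, type I interferon genes carried m6A in 74.1% of 27 tested members and a YTHDF2 peak in 92.6%, against 45.4% and 64.5% of all tested genes (Fisher's exact adjusted p 0.028 and 0.011). Expression-matched genes gave 67.2% and 87.2%, so these shares were not beyond those of other genes as highly expressed. Both marks were rare in ribosomal protein genes: 25% had an m6A peak and 40.6% a YTHDF2 peak, where matched genes gave 65.4% and 85.9%. In the oxidative phosphorylation list 19.2% and 42.3% did, where matched genes gave 60.9% and 81.1% (permutation, adjusted p = 0.0024 for each of the 4). Matching was on mean count alone, so a part played by transcript length was not separated. MHC class II genes had a YTHDF2 peak in 3 of 11, where matched genes gave 70.5% (adjusted p = 0.022), and MAPK genes in 26 of 27, where they gave 73.6% (adjusted p = 0.0096). In the MHC class I list 69.6% had m6A and 91.3% YTHDF2, where matched genes gave 68.5% and 89.4%.

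The design also asks whether marked or bound transcripts differ between genotypes. Genes with both peaks leaned to the side of Ythdf2 in the authors' deposited table, with a median log2 fold change of 0.03 against −0.07 for genes with neither, −0.03 for genes with a YTHDF2 peak alone and 0.01 for genes with m6A alone. Genes with both also had a higher median mean count than genes with neither, 1593 against 175. How much of the gap goes with expression was not measured. Against expression-matched random sets, the shift was 0.022 for 3861 genes with both, 0.023 for 4888 m6A genes and 0.0077 for 6957 YTHDF2-bound genes (permutation p = 0.0002 each, the smallest they can give). The random sets held members of the set itself, most of all for YTHDF2-bound genes, the largest set. The shifts thus understate the distance from genes outside the set and cannot be ranked against each other. cameraPR gave adjusted p-values of 8.4e-04, 8.4e-04 and 0.040. All 3 calls were lost with a preset correlation of 0.05 (adjusted p 0.18, 0.18 and 0.35), and with the stronger 50% of YTHDF2 peaks those of genes with both (shift 0.023, adjusted p 0.092) and of YTHDF2-bound genes (shift 0.0058, adjusted p 0.80) were lost. The strongest 25% gave 0.023 (adjusted p 0.28) and 0.0030 (adjusted p 0.98), and YTHDF2-bound genes also lost their call with no filter (0.0068, adjusted p 0.16) and with centring (adjusted p 0.15). The WT input libraries enter both the m6A peaks and the fold change, so these are not independent.

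**Figure D4:**
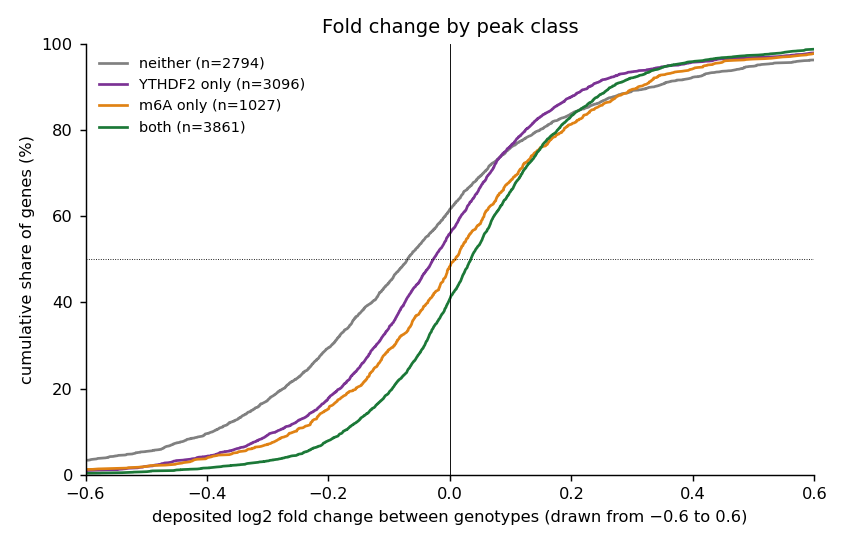
The y axis is the cumulative percent of tested genes at or below a deposited log2 fold change (x axis, drawn from −0.6 to 0.6), one line per peak class. The curve of the 3861 genes with both peaks crosses 50% at 0.03 and that of the 2794 genes with neither at −0.07.

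Changed genes carried both peaks in 95 of 190 cases on the side of Ythdf2 (50%, against 35.8% of tested genes; Fisher's exact adjusted p 1.9e-04), where expression-matched genes gave 94.4. On the opposite side they did in 23 of 60, where matched genes gave 28.1. A YTHDF2 peak, with or without m6A, was found in 35 of these 60, fewer than the 46.3 of matched genes (95% of sets between 40 and 52). Against all tested genes, 58.3% compares with 64.5% (Fisher's exact adjusted p 0.41). The other counts, 32 with m6A among these 60 and 117 with m6A and 144 with YTHDF2 among the 190, lay within the matched ranges. The largest positive changes among genes with both peaks, in the authors' deposited table, were those of Plcxd2 at 1.14 ± 0.18, Tent5c, Rassf8, Adra1a, the interleukin-7 receptor Il7r at 0.84 ± 0.14, the VEGF receptor Kdr at 0.83 ± 0.19, Ifit3b at 0.79 ± 0.14, the phosphatase Phlpp1 at 0.79 ± 0.18, H2-Q6, and Mill2 at 0.76 ± 0.23. The largest negative ones were Lyz2, Slc9a9 at −0.91 ± 0.18, Sema4c, 3110082I17Rik at −0.79 ± 0.23 and Itga9. Gbp3, Gbp4, Gbp5, Cxcl10 and Cd274, which passed the test, had both peaks, as did Irgm1, Iigp1 and Igtp at 0.34, 0.39 and 0.28, which did not pass. In the MHC class I list 15 had both, H2-Q6 among them and also H2-Q4, H2-T22, H2-K1, Tapbpl, Psmb9 and H2-D1 between 0.40 and 0.21 and the chaperone Canx at −0.21, none of these past the threshold. No MHC class II gene had both.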

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

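The alternatives on the upper 50% of genes, on centring, on preset correlations, on ranks, on exonic peaks for gene sets, on genomic span, on lists without interferon genes and on matched genes for lists among peaks were chosen after seeing the data; the others were planned. No paired analysis was possible because the deposited comparison holds no values per library. For the same reason, leaving out single libraries, other normalizations and pseudocounts, an estimated correlation and fry were not run. Stricter m6A peak sets, motif searches and matching on transcript length were not run either. Of the counts of changed genes, those outside 1.5 times the reported 190 and 60 were 37 negative genes with no filter, and 115 positive and 30 negative genes with at least 1.5-fold; fewer calls follow from more genes tested or from the added condition. Of the 8 positive and 4 negative lists, 14 positive ones were called with no filter and 2 negative ones with a correlation of 0.05; the cause was not tested. In 190 tests of single lists under alternatives, 163 kept direction and side of the threshold, 12 lost the call, 11 gained one and 4 changed direction without a call in either setting: alternative M2 (adjusted p 0.26), MAPK and cholesterol lists (0.91 each) in the upper 50%, and MAPK against matched random sets (0.55). Against matched random sets, MHC class I and NF-kB lost the call, and cell cycle, fibroblast, cholesterol and macrophage lists gained one. Of 161 named genes with an adjusted p, centring took 6 out of the calls and added 3 (Pdk1, Rpl8 and Rps4x), and no filter took out 11, the same 6 among them.

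For sets of marked or bound genes, the shift against matched genes stayed positive with other filters, peak sets and matching on span; correlations, ranks and centring cannot change it. The adjusted p-values given next are from cameraPR, which does not match on expression, while the shifts are against matched genes. YTHDF2-bound genes were no longer called with no filter (shift 0.0068, adjusted p 0.16). Nor were they with a correlation of 0.05 or with centring (0.0077 in both, adjusted p 0.35 and 0.15). The stronger 50% of peaks gave no call (0.0058, adjusted p 0.80), nor did the strongest 25% (0.0030, adjusted p 0.98, inside the range of random sets). m6A genes were not called with a correlation of 0.05 (0.023, adjusted p 0.18). Genes with both were not called with a correlation of 0.05 (0.022, adjusted p 0.18), with the stronger 50% (0.023, adjusted p 0.092) or the strongest 25% (0.023, adjusted p 0.28). With the stricter peaks their shift against matched genes was about the same, while the gap to all other genes was smaller. The random sets for a smaller set hold a smaller share of its own members. Shifts of sets of unlike size therefore cannot be compared. Medians were 0.034 against −0.035 with all peaks, 0.027 against −0.016 with the stronger 50%, and 0.021 against −0.0091 with the strongest 25%. Matching on genomic span as well gave 0.0066, 0.022 and 0.020. The count of shared genes lay between 1.04 and 1.06 times that of matched random sets in all settings. Those random sets held m6A genes too, so the ratio understates any excess over genes without m6A. The share of m6A peaks that overlap a YTHDF2 peak was 40.7% when 50% of the shorter peak had to be shared, 54.2% within 100 bp, 19.0% with the stronger 50% and 7.46% with the strongest 25% of YTHDF2 peaks, as fewer peaks or stricter rules must give. Summits lay in 3′ UTRs, coding sequence and introns in 35.6%, 33.3% and 29.5% for the stronger 50%, in 33.2%, 31.8% and 33.7% for the strongest 25%, and in 41.3%, 37.6% and 18.9% for peaks that touch an exon; the cause was not tested. Of lists among YTHDF2-bound genes, 8 were enriched and 1 depleted; this became 1 and 6 with the stronger 50% of peaks, 0 and 0 with the strongest 25%, 17 and 0 against all genes of the table, and 1 and 3 against matched genes. Among m6A genes, 4 enriched and 2 depleted lists became 16 and 0 against all genes and 0 and 2 against matched genes. Depth per library is unknown, and a median standard error of 0.167 sets what a single gene can show.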

Other observations

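Gene families, taken as symbols with the same leading letters (301 families of at least 5 tested genes), were tested with cameraPR after the data were seen, and 11 passed. The genes named here were chosen after their values were seen. Among the Slamf receptors, which sit on immune cells, Slamf1 was at 1.07 ± 0.21 in the authors' deposited table (adjusted p 1.6e-04), while Slamf7 and Slamf8 lay at 0.36 ± 0.12 and 0.31 ± 0.17 without passing (family adjusted p 0.035 over 5 genes). Ncoa4, the receptor for autophagy of ferritin, was at 0.73 ± 0.14 and its pseudogene Ncoa4-ps at 0.64 ± 0.16. These were the 2 members of the Ncoa family of 8 that passed (family adjusted p 0.048), and whether reads are shared by the pair was not tested. On the opposite side, the matrix metalloproteinases Mmp27 at −0.95 ± 0.21 and Mmp8 at −0.83 ± 0.19 passed (family of 9, adjusted p 0.029), and Mmp13 lay at −0.39 ± 0.18 and Mmp12 at 0.07 ± 0.14. Genes with the stems Eif (55, median −0.09) and Ndufa (14, median −0.15) had no single member past the threshold, with adjusted p of 0.048 each. Beside initiation factors and complex I subunits, these stems take in kinases such as Eif2ak2, the inhibitor Eif4ebp1 and pseudogenes. Within the interferon families, Ifit1bl1 at 0.73 ± 0.12, Gbp6 at 0.57 ± 0.14 and Ifi44 at 0.47 ± 0.14 were further genes on the side of Ythdf2.

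The tests of the next paragraphs were chosen after the results were seen, except the overlap bound for the names of YTHDF2 peaks, written before the overlap of positions was computed. Ythdf2 and Lyz2 lie on opposite sides of the fold change, at 1.10 and −1.49, and the authors' deposited table does not state its direction. If positive means more RNA in WT, the 1.10 is the loss of Ythdf2 RNA that a knockout predicts. Transcripts with both peaks would then be expected below other genes, yet they lay 0.022 above matched genes, the opposite sign. The bound of 0.1 for excluding this reading was chosen after the results were seen, so staying under it decides nothing. If positive means more RNA in cKO, a Cre inserted in Lyz2 (an assumption, since the labels name no Cre) may account for the −1.49 of Lyz2, but Ythdf2 RNA would have to be higher in the knockout, which a deletion of some exons with the rest of the transcript kept could allow. Reads per exon were not used here, so the readings cannot be told apart, and the direction of the interferon genes stays open with them.

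Sequences like ribosomal RNA share a positive fold change: the 7 features (CT010467.1, Gm15564, Lars2, Mir6236, Gm23935, Gm24270 and Gm24187) lay between 0.72 and 0.85 in the authors' deposited table, with single SEs of 0.11 to 0.37 from the same libraries. A higher share of cycling cells on that side stays open: the cell cycle list had a median of 0.13 ± 0.10 (SE), under the 0.5 asked for, but 12 members lay above 0 and 4 below, with Mki67 at 0.83 ± 0.19 and Cdkn1a at −0.41 ± 0.11. The list was called against matched random sets (adjusted p 0.022) and not by cameraPR (adjusted p 0.17). Unequal carry-over of ribosomal RNA through poly(A) selection stays open too. The 5 tested histone genes were taken as a probe for mRNA without a poly(A) tail. Whether their transcripts lack that tail in these cells was not checked. Their median of 0.011 ± 0.15 (SE) decides nothing. Rn7sk, an RNA without that tail, lay at 0.48 ± 0.16 (adjusted p 0.082). A difference in ribosome production between the genotypes was not tested, and the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 lay at 0.50 ± 0.13 and 0.59 ± 0.16.

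Peaks of the YTHDF2 list carry names that begin with "m6a_peak", which raises the question whether the list holds peaks of the m6A libraries. In that case at least 80% of WT m6A peaks were predicted to overlap it, and under 50% otherwise. The share was 49.0%, with a 95% Wilson interval whose upper end of 50.0 fell short of the bound by 0.00054 points. The share thus fell under the bound of 50%, but this cannot decide the question. The interval treats peaks as independent and covers counting error only, and the share within 100 bp was 54.2%, over 50% and under 80%. Whether the list holds peaks of the m6A libraries stays open. How far 2 peak callers agree on the same libraries was not tested, nor was a biological explanation.

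In the authors' deposited table Pld4 and Atp6v1c1, at 6.03 and 4.39 on the log2 scale, were followed among genes past the threshold by Gm15590 at 2.37. Neither Pld4 nor Atp6v1c1 carried an m6A or a YTHDF2 peak. Both peak lists come from WT cells, and peaks were found less often in genes of low expression. If positive means more RNA in cKO, these 2 transcripts would be scarce in WT, and the lack of peaks would say little. Of the YTHDF2 peaks in Ahnak, 6 lay at 9001586 to 9019087 on chromosome 19, among the gene's m6A peaks, and were placed in an intron of the 1 transcript that the list names.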
